A study of Mus musculus with 9 samples.

How the data were processed

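RNA from melanocyte stem cells was measured by sequencing in 9 mouse libraries, 3 from vehicle-treated, 3 from irradiated (5 Gy) and 3 from DMBA-treated animals. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a strand-marking SMARTer kit. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1. The notes give these names with no role or order. The genome build, the annotation release and whether counting used the strand are not given in the sources used here. Gene coordinates are printed as the deposited table gives them. Start and end matched a GENCODE vM21 annotation for 1494 of 52083 shared gene identifiers (2.87%), so no build is named.

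The deposited table holds whole-number read counts per gene and library, with no normalization. It also holds FPKM, which scales counts by exonic length and library total, that the authors derived from those counts. Recomputing the FPKM from the counts, the deposited exonic gene sizes and the column sums gave every value within 0.0051 in 100% of cells. Each library has a column of its own, and 0 further columns of per-sample values were left aside. Total counts per library lay between 6938406 and 8156905. The table has 55359 genes, of which 1438 carry no symbol and took between 0.121 and 0.175% of a library's counts. Mitochondrially encoded genes took between 5.05 and 7.19% of counts.

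Group and replicate number were taken from the sample titles. No pair of libraries of a group was a duplicate: chi-square per degree of freedom between 2 libraries of a group was between 15.95 and 39.7. Correlations of log2 CPM (counts scaled to a common library total) between libraries lay between 0.847 and 0.921. The labels say nothing of a shared litter, animal or day behind a replicate number.

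Counts were tested with edgeR 4.0.16 in R 4.3.3. The filter was filterByExpr, which kept 16051 genes, the scaling was TMM, and 1 mean per group was fitted over all 9 libraries with no further term. Each pair of groups was compared with edgeR's two-sided quasi-likelihood test, and a further test asked for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Expression is given as CPM, mean ± SD of 3 libraries. The biological coefficient of variation was 49%.

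Before the data were examined, 41 gene lists were written, and 38 had at least 3 tested members. List sizes given with test results count tested members only. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 38 lists. The test was repeated with an estimated correlation and with fry, which asks whether a list moves one way, or in its mixed form either way, without comparing it with other genes. Gene ontology terms in the deposited annotation with 15 to 300 tested members, 887 in all, were tested likewise. Levels of marker lists per library were compared by exact permutation, two-sided, where 3 against 3 libraries give a smallest p of 0.10.

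The rule for named genes was also written before the data were examined. It takes, per comparison, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups, a mean FPKM of at least 5 in the higher group and a symbol that is not a predicted gene. It adds up to 4 members with the smallest p of each list described, and 21 genes fixed for every comparison. Of those 21, Cdkn2a and Ptprc were removed by the count filter. Where a group has few counts, ratios of summed counts carry 95% intervals, which cover counting error only.

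On simulated counts for the 16051 genes with 200 changed, the test recovered, for IR against vehicle, 26.9% of 2-fold, 64.2% of 4-fold and 68.2% of 8-fold changes. For DMBA against vehicle the shares were 22.4, 58.2 and 69.7%, and for IR against DMBA 29.9, 59.7 and 65.2%. Unchanged genes gave 3, 8 and 3 false calls in these comparisons.

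Alternatives changed the count filter, the scaling, the libraries in the fit, the replicate number as a block, each library left out in turn, and the test itself. DESeq2 1.42.0 on counts and limma on log2(FPKM + 1) were the other tests, the latter on genes with FPKM of at least 1 in 3 libraries, also with pseudocounts of 0.1 and 5. An alternative with the basal keratinocyte level of each library as a covariate, and one with 7 libraries, were added after the data had been seen. The 7 libraries leave out vehicle 2 and IR 2, which had the lowest mean correlations with the rest (0.873 and 0.872). Values were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.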

Results

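Melanocyte stem cells are the precursors that supply pigment cells to the hair follicle. They were sorted by fluorescence from the skin of mice carrying a knocked-in Dct-H2B-GFP reporter, a fluorescent histone tied to the melanin synthesis gene Dct. The 9 RNA-seq libraries formed 3 groups of 3, from animals given vehicle, 5 Gy of ionizing radiation (IR) or DMBA, a polycyclic aromatic hydrocarbon used as a skin carcinogen. The time between treatment and sorting, and the dose and route of DMBA, are not given in the labels used here. The comparison of IR with DMBA may therefore not be matched for time or dose, and those with vehicle may not be matched for time. The groups hold no separate sham-irradiated control, and the labels used here do not say whether the IR animals also received vehicle. Depth was between 7037979 and 8156905 counts in vehicle, between 7086109 and 7958389 in IR and between 6938406 and 7871952 in DMBA libraries. The series asks what each stress does to gene expression in these cells. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

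Transcripts of the melanocyte lineage were abundant in each group. Dct averaged 3070 ± 36.9 CPM in vehicle, 2535 ± 596 in IR and 2846 ± 266 in DMBA libraries (mean ± SD, n = 3). Kit, the receptor tyrosine kinase that melanocytes depend on, averaged 1566 ± 30.6, 1794 ± 247 and 1271 ± 78.0 CPM. Keratinocyte transcripts were present as well. The summed FPKM of 16 basal keratinocyte markers was 1522 ± 300 in vehicle, 1717 ± 1459 in IR and 2899 ± 630 in DMBA libraries. The IR libraries ranged from 607.4 in IR 2 to 3369.1 in IR 1. The median log2(FPKM + 1) of these markers was 0.57 higher in DMBA than in vehicle (exact permutation p = 0.1, two-sided) and differed by -0.36 between IR and vehicle (exact permutation p = 0.7, two-sided). For differentiated epidermis markers the DMBA median was 1.16 higher (exact permutation p = 0.1, two-sided), where 0.10 is the smallest p possible. Macrophage and dendritic cell markers summed to 48.8 ± 15.9 FPKM in vehicle, 36.6 ± 16.5 in IR and 42.5 ± 2.0 in DMBA libraries. Cd68 and Epcam, which are also expressed outside immune cells, made between 79.5 and 96.8% of that sum, so it says little about immune cells. The leukocyte gene Ptprc had 0 counts in each vehicle library, 23, 3 and 7 in IR 1, 2 and 3, and 2, 9 and 0 in DMBA 1, 2 and 3. Cdkn2a had 2 counts in vehicle 3 and 0 in the rest.

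**Figure D1:**
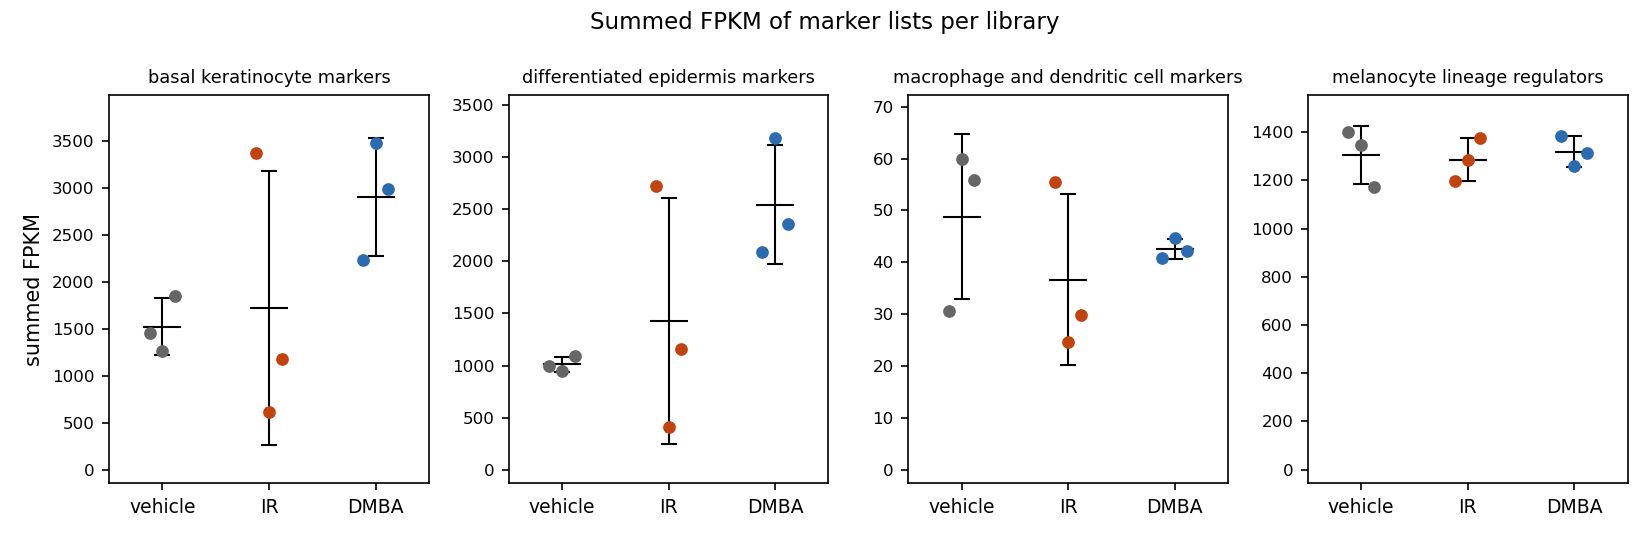
Summed FPKM (vertical axes) of basal keratinocyte, differentiated epidermis, macrophage and dendritic cell, and melanocyte lineage regulator lists in each library of the vehicle, IR and DMBA groups, with the mean (horizontal line) and SD (error bar) of 3 libraries. Basal keratinocyte sums reached 3369.1 in IR 1 and 3479.9 in DMBA 2 against 607.4 in IR 2.

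Irradiated cells carried more RNA of p53 target genes and of NF-kB response genes than vehicle cells. EdgeR called no gene of pigment synthesis or of the melanocyte regulators, whereas DESeq2 called 2 pigment genes higher. Ccng1, the p53 target that encodes cyclin G1, averaged 518.5 ± 71.0 CPM after IR and 31.6 ± 10.8 CPM in vehicle, a 16.4-fold rise. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 4.07-fold, from 213.3 ± 22.7 to 867.7 ± 72.1 CPM. Relb, an NF-kB subunit, rose 6.73-fold, from 29.07 ± 1.99 to 195.8 ± 2.75 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 118 of 16051 genes differed, 114 higher and 4 lower after IR.

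Of 36 p53 target genes tested, 20 rose and 0 fell, and 27 rose when adjusted over the list alone. The median log2 fold change was 1.99 (camera adjusted p = 1.6e-99; adjusted p = 0.0003 with an estimated correlation). Aen, a p53-induced exonuclease gene on chromosome 7 (78545602 to 78560957), had the smallest adjusted p of the named genes, with a log2 fold change of 3.96 ± 0.19 (SE; edgeR adjusted p = 5.92e-10). Ccng1, on chromosome 11 (40639379 to 40646138), had a log2 fold change of 4.04 ± 0.23 (edgeR adjusted p = 8.62e-09). Trp53inp1 rose from 86.64 ± 24.8 to 578.2 ± 67.9 CPM (edgeR adjusted p = 1.6e-07). For Cdkn1a, on chromosome 17 (29309950 to 29319701), the log2 fold change was 2.02 ± 0.16 (edgeR adjusted p = 4.15e-07). Mdm2, which encodes the ubiquitin ligase that degrades p53, rose 3.85-fold, to 441.7 ± 80.1 CPM (edgeR adjusted p = 1.53e-05). Eda2r, a receptor gene, rose from 0.547 ± 0.577 to 40.55 ± 3.54 CPM (edgeR adjusted p = 0.000125). Gtse1 rose 17.7-fold, and Ephx1, which encodes an epoxide hydrolase, rose 7.19-fold. Trp53 itself had a log2 fold change of 0.78 and did not pass (edgeR adjusted p = 0.145).

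Other large rises were outside the p53 list. Isg20, an interferon-induced exonuclease gene, had 2 counts over the vehicle libraries and 599 over the IR libraries, a ratio of 302.3 (95% counting interval 83.3 to 2500). Its nearest neighbour Aen lies 2214 bases away and also rose. Dyrk3, a protein kinase gene, averaged 50.06 ± 7.7 CPM after IR and 1.48 ± 2.44 CPM in vehicle. Inka2 averaged 137.9 ± 6.57 against 7.309 ± 4.82 CPM, and Zfp469 222.0 ± 25.3 against 13.67 ± 9.1 CPM. Ifi47, an interferon-inducible GTPase gene, averaged 15.75 ± 8.89 against 0.636 ± 0.547 CPM. Reads of Ifi47 can overlap Olfr56, so its count is uncertain.

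Of 19 NF-kB response genes tested, 11 rose and 0 fell, and 15 rose when adjusted over the list alone. The median log2 fold change was 1.96 (camera adjusted p = 2.47e-53; adjusted p = 0.000102 with an estimated correlation). Relb had a log2 fold change of 2.75 ± 0.19 (edgeR adjusted p = 1.27e-07). Csf1, which encodes macrophage colony-stimulating factor, rose from 37.74 ± 8.27 to 248.1 ± 34.0 CPM (edgeR adjusted p = 2.26e-06). Nfkb2 rose 3.02-fold, to 505.7 ± 29.6 CPM, and Nfkbia, which encodes an inhibitor of NF-kB, rose 2.86-fold, to 415.4 ± 41.0 CPM.

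Antigen presentation and interferon-stimulated genes were also higher as lists at the preset correlation, but neither list was called with an estimated one (adjusted p = 0.272 for each). Of 20 antigen presentation genes, 3 rose (Tapbp, H2-Q4 and Psmb8), 0 fell, 13 rose when adjusted over the list alone, and 20 had a positive log2 fold change. The camera adjusted p was 1.11e-14. Tapbp, the tapasin gene, rose from 78.77 ± 9.94 to 211.3 ± 74.0 CPM, and H2-Q4, a class I gene, rose from 199.3 ± 48.2 to 409.7 ± 137 CPM. Class I genes are near-identical paralogs and Tapbp overlaps Zbtb22, so these counts are uncertain. H2-K1 did not pass (874.7 ± 488 against 394.7 ± 54.8 CPM; edgeR adjusted p = 0.0547). Its highest level, 1420 CPM, was in IR 1, the IR library with the most basal keratinocyte RNA. Of 30 interferon-stimulated genes, 2 rose (Ifi47 and Parp14) and 0 fell; adjusted over the list alone 8 rose and 1 fell. The list's camera adjusted p was 1.8e-09.

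Of 27 apoptosis regulators, 6 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.94e-07; adjusted p = 0.0323 with an estimated correlation). Of these 6, 3 are also on the p53 list and 1 is on the NF-kB list. Over all 27 regulators the median log2 fold change was 0.31, and 19 were positive. Apaf1, which encodes the apoptosome scaffold, rose 2.99-fold, to 221.4 ± 30.6 CPM. Birc3, which encodes an inhibitor of apoptosis, rose 5.69-fold, to 273.4 ± 18.3 CPM. Bbc3, which encodes the BH3-only protein PUMA, rose 3.20-fold, and the death receptor gene Fas rose 6.87-fold. Of 18 secretory factors of senescence tested, from 45 on the list, 3 rose, 0 fell and 4 rose when adjusted over the list alone. These were Csf1 and Icam1, both also on the NF-kB list, and the matrix metalloproteinase gene Mmp2 (44.08 ± 11.4 against 2.901 ± 2.53 CPM). The camera adjusted p was 4.12e-05, but adjusted p = 0.0777 with an estimated correlation. Of 14 cell cycle inhibitors, only Cdkn1a rose and 0 fell, with 3 higher when adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.316 with an estimated correlation). That list was called in 12 of 23 alternatives (adjusted p up to 0.392), not by limma, with no filter, with 7 libraries or without vehicle 3 or IR 2.

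The 4 lower genes included the neuronal navigator gene Nav1, which fell from 819.2 ± 53.1 to 411.2 ± 74.1 CPM (edgeR adjusted p = 0.0023). Gucy1b1, a guanylate cyclase subunit gene, fell as well and had a log2 fold change of -0.72 ± 0.16 (edgeR adjusted p = 0.0422). The other 2, chosen after their values were seen, were the adrenergic receptor gene Adra1a (log2 fold change -1.95) and the predicted gene Gm2115 (-1.13). Of 26 immediate early genes, edgeR called 0, DESeq2 called 2 lower and limma called 0. At an unadjusted p under 0.05, 1 was higher and 8 were lower; adjusted over the list alone 1 rose and 5 fell. The list ranked lower by camera (adjusted p = 0.00338; adjusted p = 0.651 with an estimated correlation), except without IR 3 or with 7 libraries (adjusted p up to 0.0912). Fosb averaged 3998 ± 282 CPM after IR and 5973 ± 648 CPM in vehicle, and Egr1 1636 ± 235 against 2330 ± 277 CPM. Of 31 mitotic genes, edgeR, DESeq2 and limma called 0, 0 were called when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. The mitotic list ranked lower by camera (adjusted p = 0.00845; adjusted p = 0.651 with an estimated correlation), except without vehicle 1 or vehicle 3 (adjusted p up to 0.177). Mki67 averaged 18.68 ± 21.4 against 61.67 ± 34.4 CPM. Of 26 NRF2 antioxidant genes, edgeR, DESeq2 and limma called 0, also over the list alone, and 4 were higher at an unadjusted p under 0.05. That list ranked higher by camera (adjusted p = 0.0285; adjusted p = 0.316 with an estimated correlation), except without vehicle 2, vehicle 3 or IR 1, with 7 libraries and with array weights (adjusted p up to 0.205).

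EdgeR called no gene on the lists of pigment cells after IR. Of 39 pigment synthesis and melanosome genes, edgeR called 0, also over the list alone, and limma called 0, while DESeq2 called 2 higher. At an unadjusted p under 0.05, 3 were higher and 2 lower (camera adjusted p = 0.621), with a median log2 fold change of -0.14 and a mean of 0.07. Tyrp1 had a log2 fold change of 0.53 (edgeR adjusted p = 0.214), Tyr -0.55 (0.307) and Pmel 0.40 (0.623). Of 24 melanocyte lineage regulators, edgeR, DESeq2 and limma called 0, also over the list alone, and 1 was higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.546). Fry's mixed test, which counts changes in either direction, called both lists (adjusted p = 0.0481 for pigment genes and 0.00592 for lineage regulators). Mitf, the master regulator of the lineage, averaged 792.8 ± 105 against 1006 ± 96.6 CPM, and Sox10 496.1 ± 81.1 against 442.8 ± 70.7 CPM. Of 35 genes of DNA damage signalling and repair, edgeR called 0, also over the list alone, limma called 0 and DESeq2 called 1 higher, with 3 higher and 1 lower at an unadjusted p under 0.05.

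**Figure D2:**
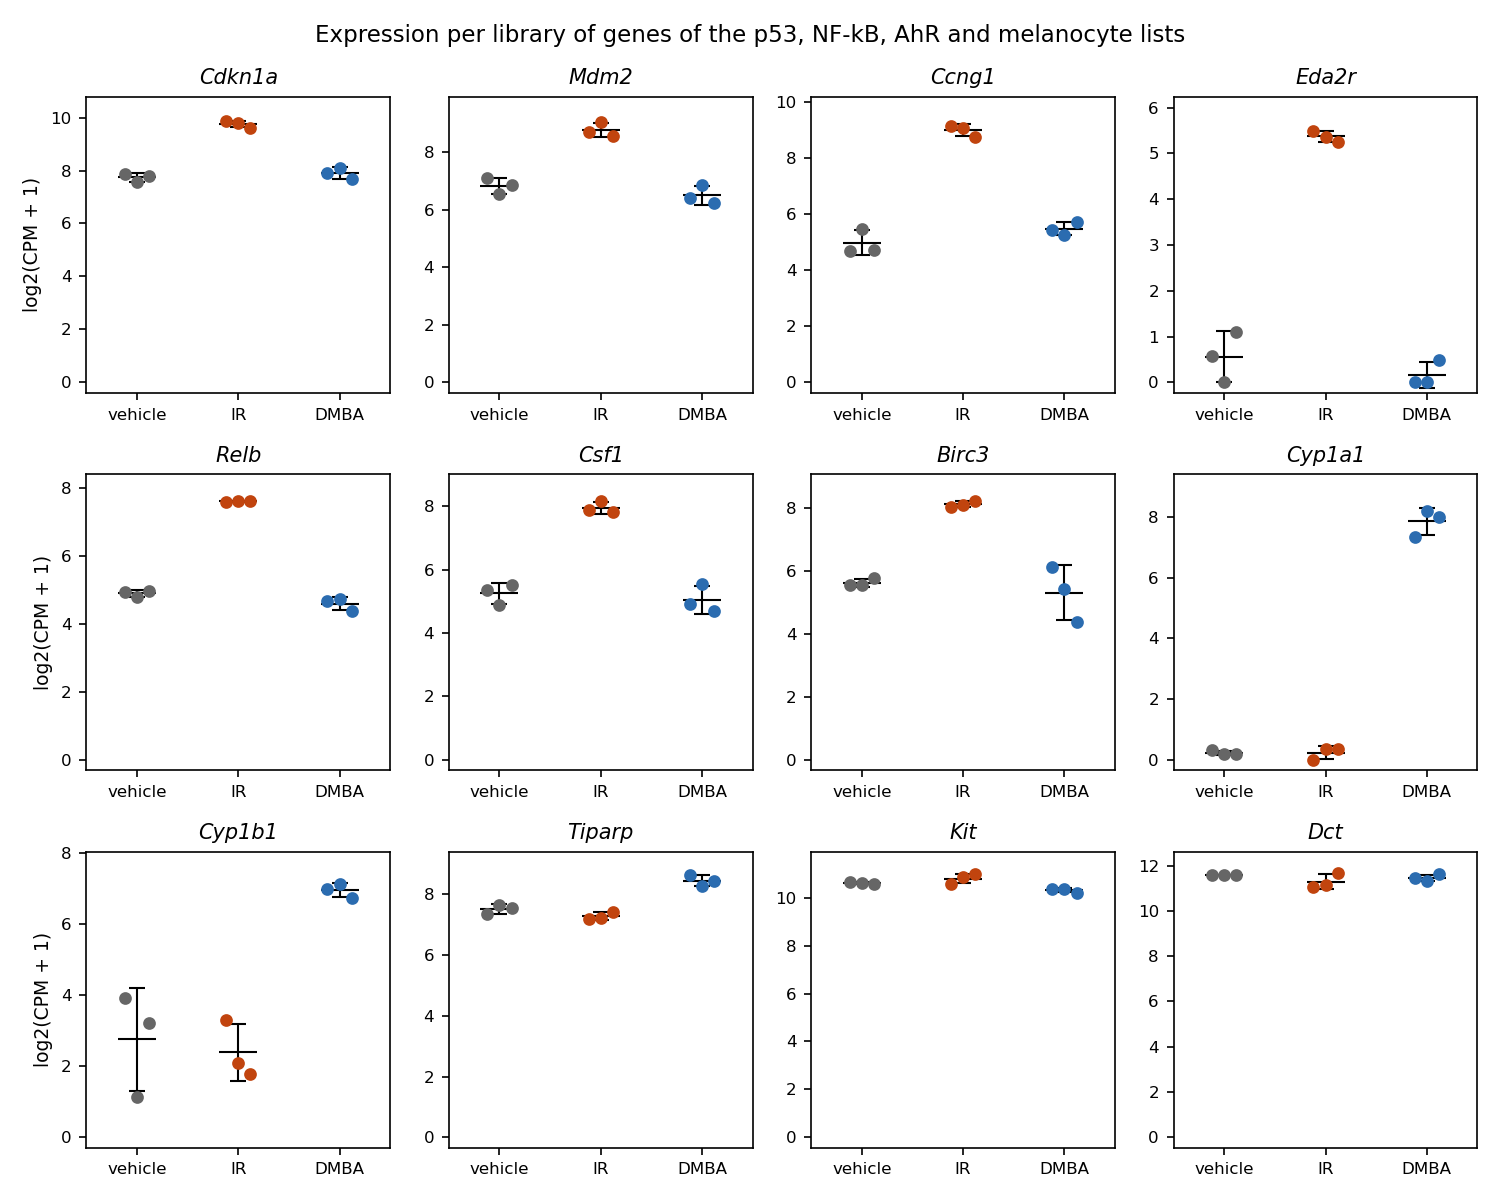
Expression as log2(CPM + 1) of 12 genes in each library of the vehicle, IR and DMBA groups, with the mean (horizontal line) and SD (error bar) of 3 libraries. The p53 targets Cdkn1a, Mdm2, Ccng1 and Eda2r and the NF-kB response genes Relb, Csf1 and Birc3 are higher in IR, and Cyp1a1, Cyp1b1 and Tiparp are higher in DMBA.

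In each of the 118 called genes the 3 IR libraries did not overlap the 3 vehicle libraries, a pattern found in 13.8% of all genes tested and in 10% by chance. At an unadjusted p under 0.05, 791 genes were higher and 535 lower, where 803 in all are expected by chance. Of 38 lists, camera called 10, and 3 were called with an estimated correlation: p53 targets, NF-kB response and apoptosis. Of 887 gene ontology terms, camera called 0, with 45 at an unadjusted p under 0.05, and 0 with an estimated correlation. The count of 118 depended on the test (251 by DESeq2, 86 by limma) and on the filter (236 with none), and was 76 without vehicle 3 and 63 with the 7 libraries that leave out vehicle 2 and IR 2, an alternative chosen after the data were seen. The count of lower genes moved more: 4 became 32 by DESeq2, 27 with no filter, 20 without IR 1 and 22 with the keratinocyte covariate, also chosen after, and 1 with the 7 libraries. Of 30 named called genes, 17 kept their call in every alternative, among them Aen, Ccng1, Cdkn1a, Mdm2, Relb, Csf1 and Isg20, whereas Gucy1b1, H2-Q4, Psmb8, Bbc3, Fas, Parp14, Icam1 and Ifi47 each lost it when some single library was left out.

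DMBA-treated cells differed from vehicle cells most in genes of the aryl hydrocarbon receptor (AhR), the receptor that binds polycyclic aromatic hydrocarbons. Cyp1a1, a cytochrome P450 gene and the textbook AhR target, had 4 counts over the vehicle libraries and 5449 over the DMBA libraries, a ratio of 1342 (95% counting interval 524 to 4930). Cyp1b1, another AhR-regulated cytochrome P450 gene, rose from 7.84 ± 6.46 to 122.6 ± 16.4 CPM. Transcripts of keratinocytes and of differentiated epidermis were also higher as lists at the preset correlation, but neither list was called with an estimated one (camera adjusted p = 0.684 and 0.491). EdgeR called no single member, while DESeq2 called 1 differentiated epidermis marker. The p53 target genes that rose after IR did not pass the test: Cdkn1a averaged 239.8 ± 36.0 CPM after DMBA and Mdm2 91.03 ± 20.9 CPM, against 213.3 ± 22.7 and 114.7 ± 21.7 CPM in vehicle.

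By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 16051 genes rose with DMBA and 0 fell. Cyp1a1, on chromosome 9 (57595211 to 57611107), had a log2 fold change of 10.27 ± 0.43 (SE; edgeR adjusted p = 7.15e-11), averaging 238.6 ± 67.9 CPM. Cyp1b1 had a log2 fold change of 3.96 ± 0.55 (edgeR adjusted p = 0.00868). Adh7, an alcohol dehydrogenase gene, rose from 4.33 ± 3.27 to 71.07 ± 24.6 CPM (edgeR adjusted p = 0.00916). Plcg2, a phospholipase C gene, rose 3.47-fold, to 60.58 ± 9.85 CPM (edgeR adjusted p = 0.027). Tiparp, an AhR-induced ADP-ribosyltransferase gene, rose 1.91-fold, to 348.8 ± 43.9 CPM (edgeR adjusted p = 0.0358). The sixth, Isg20, chosen after its values were seen, averaged 5.23 ± 2.31 against 0.0958 ± 0.166 CPM (edgeR adjusted p = 0.0207). Of 16 AhR and xenobiotic response genes, 3 rose (Cyp1a1, Cyp1b1 and Tiparp), 0 fell and 7 rose when adjusted over the list alone. The list's median log2 fold change was 1.41 (camera adjusted p = 2.14e-23; adjusted p = 0.00122 with an estimated correlation). Aldh3a1, an aldehyde dehydrogenase gene of this list, averaged 99.98 ± 30.0 against 11.57 ± 3.11 CPM but did not pass (edgeR adjusted p = 0.126).

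The epidermal lists were higher in the group with the higher basal marker sum, which was 2899 ± 630 FPKM in DMBA and 1522 ± 300 FPKM in vehicle. Of 15 differentiated epidermis markers, edgeR called 0 and limma 0, DESeq2 called 1, 5 rose when adjusted over the list alone and 10 were higher at an unadjusted p under 0.05. The camera adjusted p was 1.98e-11, but adjusted p = 0.491 with an estimated correlation. Krt1 averaged 1128 ± 328 against 392.6 ± 79.6 CPM, Krt10 1936 ± 469 against 729.8 ± 99.9 CPM and Casp14 20.13 ± 5.22 against 4.728 ± 1.44 CPM. Of 16 basal keratinocyte markers, edgeR, DESeq2 and limma called 0, also over the list alone, 9 were higher at an unadjusted p under 0.05 and 16 had a positive log2 fold change. The camera adjusted p was 5.98e-09, but adjusted p = 0.684 with an estimated correlation. Krt14, a basal keratin gene, averaged 1225 ± 285 against 639.5 ± 78.9 CPM, and Dsp, the desmoplakin gene, 2834 ± 597 against 1454 ± 331 CPM. Of 12 sebaceous gland markers, edgeR, DESeq2 and limma called 0, 4 rose when adjusted over the list alone and 4 were higher at an unadjusted p under 0.05. For them the camera adjusted p was 0.000303, but adjusted p = 0.684 with an estimated correlation; Elovl4 averaged 107.0 ± 93.1 against 28.31 ± 5.39 CPM.

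Arachidonic acid, NRF2 antioxidant and ribosomal protein genes ranked higher by camera too, at the preset correlation only. Of 33 arachidonic acid genes, edgeR, DESeq2 and limma called 0, also over the list alone, and 8 were higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00442; adjusted p = 0.491 with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, averaged 19.01 ± 6.51 against 4.776 ± 3.57 CPM (edgeR adjusted p = 0.717), and Pla2g2f 59.39 ± 19.6 against 27.34 ± 3.81 CPM. Of 26 NRF2 antioxidant genes, edgeR, DESeq2 and limma called 0, also over the list alone, and 3 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.0121; adjusted p = 0.491 with an estimated correlation). Of 47 ribosomal protein genes, edgeR, DESeq2 and limma called 0, also over the list alone, and 3 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.006; adjusted p = 0.753 with an estimated correlation). With the basal keratinocyte level as a covariate, chosen after the data were seen, these 3 lists and the sebaceous list were no longer called. Their adjusted p was then 0.349 for arachidonic acid, 0.072 for NRF2, 0.812 for ribosomal protein and 0.0773 for sebaceous genes. The covariate is made of the basal keratinocyte markers, which the differentiated markers follow, so it cannot test those lists. For the other lists it is limited too, since these markers part the groups. Their mean log2(FPKM + 1) lay between 5.161 and 5.693 in vehicle and between 5.884 and 6.48 in DMBA libraries. A lost call therefore cannot tell keratinocyte content from an effect of DMBA. Leaving out 1 library ended the call of the sebaceous list (DMBA 2), the arachidonic acid list (vehicle 1), the NRF2 list (vehicle 2 or DMBA 2) and the ribosomal list (vehicle 3 or DMBA 3).

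Melanocyte genes did not pass in DMBA, although fry's mixed test called the lineage regulators (adjusted p = 0.0405). Kit had a log2 fold change of -0.30 (edgeR adjusted p = 0.718), Sox10 0.33 (0.745) and Dct -0.11, and Mitf averaged 918.9 ± 184 against 1006 ± 96.6 CPM. Of 36 p53 target genes, edgeR, DESeq2 and limma called 0, also over the list alone, and 5 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.141). Mki67, the proliferation marker, averaged 57.5 ± 29.3 against 61.67 ± 34.4 CPM.

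At an unadjusted p under 0.05, 618 genes were higher and 458 lower in DMBA, where 803 in all are expected by chance, and 13.7% of all genes had non-overlapping groups against 10% by chance. Of 38 lists, camera called 7, and only the AhR list was called with an estimated correlation. Of 887 gene ontology terms, camera called 6, all higher, among them skin development (adjusted p = 0.00147), keratinocyte differentiation (adjusted p = 0.0291) and desmosome (adjusted p = 0.0291), and each had adjusted p = 0.941 with an estimated correlation. The count of 6 was 23 (21 higher, 2 lower) by DESeq2, 1 by limma, 44 with the 6 libraries compared and 159 with no filter, and it was 2 without vehicle 1 or DMBA 3, 3 without vehicle 2 or DMBA 1, 25 without IR 1 and 16 without IR 2. Cyp1a1 kept its call in every alternative and Cyp1b1 with each library left out. Adh7 and Isg20 lost theirs without vehicle 1 or DMBA 3, and with Isg20 the overlap with the IR calls was lost. Plcg2 and Tiparp (adjusted p up to 0.223 and 0.353) lost the call when some single library was left out. The keratinocyte covariate, which parts the DMBA from the vehicle libraries, also ended the call of Plcg2.

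The direct comparison of the treatments uses no vehicle library in its contrast. IR cells carried more RNA of p53 target and NF-kB response genes, and of some apoptosis regulators, than DMBA cells, and less of the AhR genes. Eda2r had 3 counts over the DMBA libraries and 909 over the IR libraries, a ratio of 310.5 (95% counting interval 106 to 1510). Cyp1a1 had 4 counts over the IR libraries and 5449 over the DMBA libraries, a ratio of 0.000752 (95% counting interval 0.000205 to 0.00193). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 157 genes differed, 141 higher and 16 lower in IR.

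Of 36 p53 target genes, 18 were higher and 0 lower in IR, and adjusted over the list alone 26 were higher and 2 lower (camera adjusted p = 3.47e-80; adjusted p = 0.00027 with an estimated correlation). Aen averaged 309.7 ± 28.8 CPM in IR and 21.0 ± 1.65 CPM in DMBA (edgeR adjusted p = 3.84e-10). Inka2 averaged 137.9 ± 6.57 against 2.798 ± 1.81 CPM, and Ccng1 518.5 ± 71.0 against 44.25 ± 7.55 CPM. Cdkn1a was 3.62-fold and Mdm2 4.85-fold higher in IR. Trp53 was higher in IR (97.18 ± 14.6 against 51.13 ± 12.4 CPM; edgeR adjusted p = 0.0462), a call that 17 alternatives ended. The transcription factor gene Mybl1 was 11.9-fold higher in IR.

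Of 19 NF-kB response genes, 10 were higher and 0 lower in IR, with 14 higher when adjusted over the list alone (camera adjusted p = 2.43e-51; adjusted p = 0.000114 with an estimated correlation). Relb was 8.33-fold, Csf1 7.44-fold, Nfkbie 6.41-fold and Nfkb2 2.95-fold higher. Of 27 apoptosis regulators, 5 were higher and 0 lower, with 8 higher when adjusted over the list alone (camera adjusted p = 2.9e-09; adjusted p = 0.0128 with an estimated correlation). Birc3 was 6.30-fold, Apaf1 3.63-fold, Bax 4.43-fold and Birc2 2.57-fold higher. Birc3 is also on the NF-kB list and Bax on the p53 list. Over all 27 regulators the median log2 fold change was only 0.15, and 18 were positive, so the rise was in some members. Of 30 interferon-stimulated genes, 4 were higher, 0 lower and 13 higher when adjusted over the list alone (camera adjusted p = 1.41e-11; adjusted p = 0.166 with an estimated correlation). Of 20 antigen presentation genes, 4 were higher, 0 lower and 9 higher when adjusted over the list alone (camera adjusted p = 2.43e-11; adjusted p = 0.224 with an estimated correlation). Tap1, a peptide transporter gene, was 2.57-fold higher, and Gbp2, a guanylate-binding protein gene, 3.98-fold higher (147.7 ± 122 against 37.08 ± 9.25 CPM).

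Of 16 AhR and xenobiotic response genes, 4 were lower and 1, Ephx1, which is also on the p53 list, was higher in IR, and adjusted over the list alone 7 were lower and 1 higher (camera adjusted p = 8.18e-15; adjusted p = 0.00165 with an estimated correlation). Cyp1b1 averaged 4.816 ± 3.43 CPM in IR and 122.6 ± 16.4 CPM in DMBA, and Aldh3a1 12.29 ± 15.6 against 99.98 ± 30.0 CPM. Tiparp averaged 154.1 ± 13.8 against 348.8 ± 43.9 CPM (edgeR adjusted p = 0.000266). Igfbp3, which encodes an insulin-like growth factor binding protein, averaged 16.64 ± 14.2 against 143.4 ± 21.6 CPM. Adh7 (log2 fold change -2.84) and Plcg2 (-1.65) were lower as well. Hebp1 (-1.91) was lower too, but its reads can overlap Fam234b. Of 24 lineage regulators, Mef2c was lower (65.08 ± 9.76 against 117.5 ± 20.6 CPM; edgeR adjusted p = 0.0432) and 0 were higher, while adjusted over the list alone 3 were higher and 3 lower (camera adjusted p = 0.58; fry mixed adjusted p = 6.84e-06). Kit averaged 1794 ± 247 against 1271 ± 78.0 CPM and did not pass (edgeR adjusted p = 0.099).

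The basal keratinocyte sum was 1717 ± 1459 FPKM in IR and 2899 ± 630 FPKM in DMBA, and epidermal lists ranked lower in IR. Of 16 basal keratinocyte markers, edgeR, DESeq2 and limma called 0, also over the list alone, 4 were lower at an unadjusted p under 0.05 and 0 had a positive log2 fold change (camera adjusted p = 9.77e-08; adjusted p = 0.375 with an estimated correlation). Of 15 differentiated epidermis markers, edgeR, DESeq2 and limma called 0, also over the list alone, and 4 were lower at an unadjusted p under 0.05 (camera adjusted p = 4.32e-07; adjusted p = 0.375 with an estimated correlation). Krt14 averaged 722.5 ± 597 against 1225 ± 285 CPM.

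Of 38 lists, camera called 17, 9 higher and 8 lower in IR, and 4 were called with an estimated correlation: p53 targets, NF-kB response, AhR and apoptosis. Lists called only at the preset correlation, with adjusted p between 0.186 and 0.489 at an estimated one, also took in senescence secretory factors, cell cycle inhibitors, the unfolded protein response and endothelial markers (higher) and hair follicle stem cell, mitotic, arachidonic acid, immediate early and histone genes (lower). Of 18 secretory factors, edgeR called 2 higher and 1, Igfbp3, lower. Only 8 of them had a positive log2 fold change, and their median was -0.07, so that list did not rise as a whole. Of 23 alternatives, 10 kept the call of the unfolded protein response (adjusted p up to 0.219) and 14 that of the cell cycle inhibitors (up to 0.173). Leaving out 1 library ended the call of the secretory factors (IR 1), immediate early genes (IR 3 or DMBA 2), histone genes (IR 3 or DMBA 3) and unfolded protein response (IR 1, IR 3, DMBA 1 or DMBA 3). The keratinocyte covariate, chosen after the data were seen, ended 7 calls outside the epidermal lists: arachidonic acid and immediate early genes (adjusted p = 0.243 for each), histone genes (0.236), hair follicle stem cell (0.3), mitotic (0.0574) and endothelial genes (0.0602) and cell cycle inhibitors (0.076). Gene ontology gave 3 of 887 terms, heat shock protein binding, phosphatidylinositol trisphosphate binding and the response to interferon-beta, all higher, and 0 with an estimated correlation; 76 had an unadjusted p under 0.05. The count of 157 was 310 by DESeq2, 89 by limma and 371 (243 higher, 128 lower) with no filter, and it was 421 (206 higher, 215 lower) without IR 1, 99 without IR 2 and 96 without DMBA 3. Of 44 named called genes, 19 kept their call in every alternative, among them Aen, Ccng1, Mybl1, Relb, Cyp1a1, Cyp1b1 and Tiparp, whereas Igfbp3, Aldh3a1, Adh7, Hebp1, Gbp2, Mef2c and Ifi47 each lost it when some single library was left out.

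The test for any difference among the 3 groups called 171 genes, of which 160 were also called in a pairwise comparison. The other 11 included Gdf15, Ahrr, Cyba and Xdh, chosen after their values were seen. This count was 341 by DESeq2, 89 by limma, 485 with no filter, 388 without IR 1 and 111 with the 7 libraries. Of the 118 genes called between IR and vehicle, 86 were also called in the same direction between IR and DMBA. The 114 genes higher in IR had a median log2 fold change of 1.70 in IR and 0.07 in DMBA. Isg20 alone was called higher against vehicle in both treatments, where independent lists give 0.043 genes. Simulated unchanged groups against the shared vehicle libraries gave a mean of 0.02 and a range of 0 to 1. They hold no changed genes, unlike the data, so they cannot tell whether an overlap of 1 gene exceeds chance. At an unadjusted p under 0.05, 174 genes were higher in both (simulated mean 112.68, range 94 to 136; independent lists 30.5) and 85 lower in both (simulated mean 55.28; independent lists 15.3), while 15 moved in opposite directions (simulated mean 0.96, range 0 to 4). Of all genes 67.0% had the same sign in both, inside the simulated range of 65.6 to 67.5%. Across genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.542 against 0.503 simulated, and their covariance was 0.461 against 0.346, a difference of 0.115. The correlation and the covariance lay above their simulated ranges, which ended at 0.534 and 0.378. The 3 vehicle libraries cannot be split into sets of at least 2, so no overlap free of shared controls was measured. The simulated groups share their vehicle libraries too, so the simulated values already include that effect. The cause of the excess over them was not tested.

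**Figure D3:**
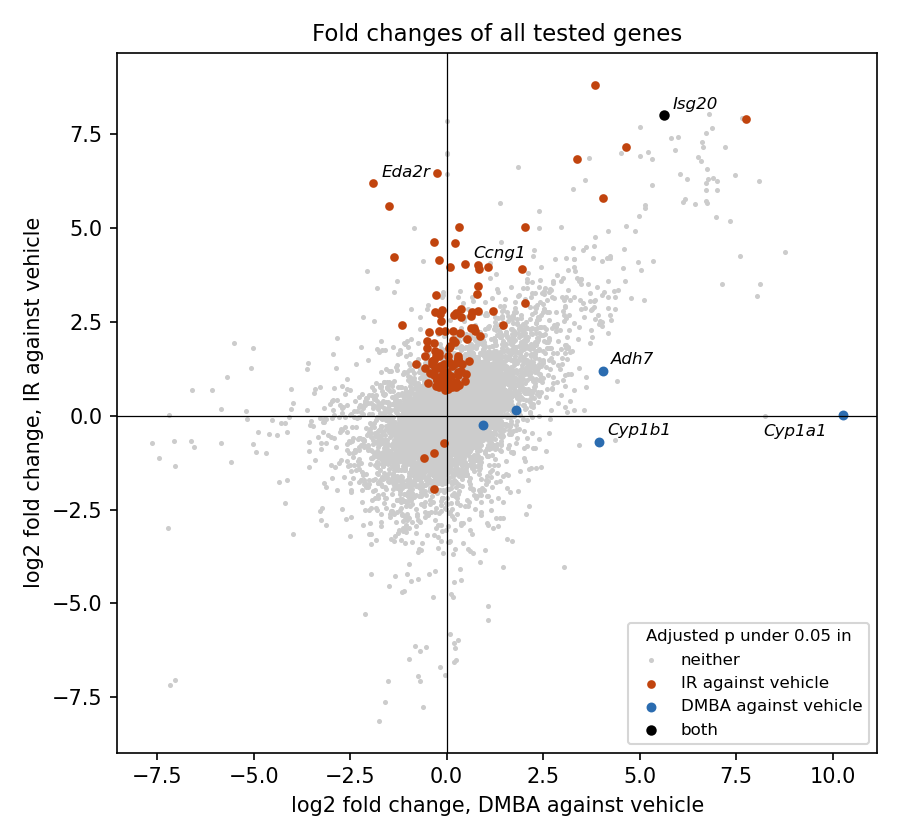
Log2 fold change against vehicle of the 16051 tested genes, DMBA on the horizontal and IR on the vertical axis, with 1 point per gene coloured by the comparison in which its adjusted p was under 0.05. Cyp1a1 and Cyp1b1 lie far along the DMBA axis near 0 on the IR axis, Eda2r and Ccng1 lie high on the IR axis, and Isg20 is called in both.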

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

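The tests with the basal keratinocyte level as a covariate, with 7 libraries and with an estimated correlation for gene ontology terms were chosen after the data had been seen. No named gene that passed the test changed sign in any alternative: over the 3 comparisons 108, 44 and 195 single values lost the call and 48, 50 and 79 gained it (IR against vehicle, DMBA against vehicle, IR against DMBA). The p53, NF-kB, apoptosis, interferon, antigen presentation and secretory factor lists (IR against vehicle) and the AhR list (DMBA against vehicle) were called by camera at the preset correlation in all 23 alternative fits. Of these, the interferon and antigen presentation lists (adjusted p = 0.272 for each) and the secretory factors (0.0777) were not called with an estimated correlation. With no filter the counts were 236, 159 and 371 in these comparisons and 485 among the 3 groups. Only 0, 1 and 0 of the calls in these comparisons were on genes that the filter removes, and the prior degrees of freedom of the variance were infinite. DESeq2 gave 251, 23, 310 and 341 genes, which included 118, 6, 152 and 167 of the genes called by edgeR. Values on log2(FPKM + 1) in limma were 86, 1, 89 and 89. Pseudocounts of 0.1 gave 69, 1, 73 and 72 and pseudocounts of 5 gave 86, 2, 101 and 109. Quantile normalization gave 81, 2, 95 and 94, TPM scaling 71, 1, 81 and 86, no trend 56, 1, 68 and 67, and array weights 89, 2, 115 and 108. A fit of the 6 libraries compared gave 44 genes for DMBA. The keratinocyte covariate gave 178 genes for IR, and 2 lists for DMBA and 8 for IR against DMBA in place of 7 and 17. The loss of the basal keratinocyte list there is fixed by the covariate, which is made of its markers. The 7 libraries gave 63 genes for IR and 111 among the 3 groups. For each of these differences the cause was not tested.

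Leaving out each library in turn gave between 76 (without vehicle 3) and 131 genes for IR, between 2 (without vehicle 1 or DMBA 3) and 25 (without IR 1) for DMBA, between 96 (without DMBA 3) and 421 (without IR 1) for IR against DMBA, and between 129 and 388 (without IR 1) among the 3 groups. Omitting vehicle 2, DMBA 1 or IR 2 also moved the DMBA count by over 1.5 times, and omitting IR 2 the count for IR against DMBA. The lists called by camera were then between 7 and 13, between 6 and 9, and between 14 and 20. IR 1 held the most basal keratinocyte RNA of the IR libraries, and without it the biological coefficient of variation was 52.8% against 49%, while the prior degrees of freedom rose from 12.05 to 18.63; the cause was not tested. With an estimated correlation, and with fry for 1 direction, the lists called were 3, 1 and 4. Fry's mixed test called 12, 5 and 12 lists, of which 7, 2 and 8 were also called by camera at the preset correlation. With an estimated correlation the gene ontology terms fell to 0 in DMBA against vehicle (from 6) and to 0 in IR against DMBA (from 3). At an unadjusted p under 0.05 the overlap of the comparisons against vehicle was 259 genes in place of 1, at the looser threshold. With the replicate number as a block the counts were 107, 5, 142 and 156, and the lists 11, 7 and 17. The numbers do not pair the libraries: deviations from the group means of libraries with the same number correlated between -0.0866 and 0.0415, and of other pairs between -0.0538 and 0.101. DESeq2 gives no list test, and the test among the 3 groups was not run on 6 libraries.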

Other observations

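The tests of explanations below, and the immune cell markers used in them (macrophage, dendritic, T, NK and mast cell lists and Ptprc, without Cd68 and Epcam), were chosen after the results had been seen, except the counts of other groupings of the libraries. Of the 114 genes higher after IR, 74 were on none of the lists, and the following were chosen after their values were seen. Surface and signalling genes were among them: Cd44, an adhesion receptor gene, had a log2 fold change of 0.98 ± 0.16 (SE; edgeR adjusted p = 0.0023), and Piezo1, a mechanosensitive channel gene, 1.02 ± 0.16 (edgeR adjusted p = 0.00163). Cd274, which encodes the immune checkpoint ligand PD-L1, had 0.94 ± 0.21 (edgeR adjusted p = 0.0444), and Fat1, a large cadherin gene, 1.79 ± 0.17 (edgeR adjusted p = 3.62e-06). Map3k20, a stress-activated kinase gene, had 2.26 ± 0.18 (edgeR adjusted p = 4.49e-07), Abcb1b, an efflux transporter gene, 3.90 ± 0.65 (edgeR adjusted p = 0.00297), and Ddias 3.25 ± 0.48 (edgeR adjusted p = 0.000975).

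Predicted genes moved with IR as well. Gm42047, on chromosome 8 (122559986 to 122567917), averaged 870 ± 205 CPM after IR against 35.4 ± 7.27 CPM in vehicle and 28.1 ± 12.9 CPM in DMBA, a log2 fold change of 4.62 against vehicle (edgeR adjusted p = 2.45e-08). Of 5 predicted genes called in IR against vehicle, 4 were higher. Gm13067 and Gm37795, both higher, lie 11562 bases apart on chromosome 4. Among genes higher after IR there were 5 neighbouring pairs within 20000 bases, including Aen and Isg20 (2214 bases) and Birc2 and Birc3 (11634 bases). In 1000 random sets matched on expression the mean was 0.71 pairs, the highest 4, and 0 sets had as many. Both the count of pairs and the limit of 20000 bases were chosen after the pairs had been seen. Of 189 genes called in any comparison, 19 overlap another gene whose counts reach a set share of their own, so their counts are uncertain. Overlaps with genes of fewer counts were left out of this number.

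The p53 and NF-kB genes higher after IR may reflect a response in the sorted cells or RNA of other cells. Against a response only in carried-over keratinocytes, the 31 called members had a median slope of -0.02 (quartiles -0.08 and 0.04) on the basal keratinocyte level. That level differed 5.55-fold over the 3 IR libraries. Single slopes ranged from -0.255 (Bbc3) to 0.502 (Icam1), with Vcam1 (0.392) and Tnfaip3 (0.332) next highest. Icam1, Vcam1 and Tnfaip3 are all on the NF-kB list, so the median does not speak for each member. The keratinocyte markers had a slope of 0.98, but the level is made of them, so a slope near 1 was fixed beforehand. Slopes of members not called were not computed. A gene that followed the keratinocyte level would vary more within IR and pass less easily, so the slopes speak for the called members only. Against a difference in keratinocyte content, 31 of 31 members stayed past the threshold with the keratinocyte covariate, at a median log2 fold change of 2.25 before and after. For more immune cells as the cause, the log2 ratio of IR to vehicle of summed immune cell markers, without Cd68 and Epcam, was -0.33 (SE 0.57). No rise was seen, but with 3 libraries per group and this SE a rise cannot be excluded. The summed counts were 159, 388 and 151 in vehicle 1, 2 and 3 and 284, 123 and 132 in IR 1, 2 and 3. The negative sign thus leans on vehicle 2. The leukocyte gene Ptprc alone had 0 counts in each vehicle library and 23, 3 and 7 in the IR libraries. A response only in carried-over immune cells cannot be told apart from one in the sorted cells, which stays open, because those markers differed only 2.21-fold between the highest and lowest IR libraries.

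The keratinocyte and epidermal transcripts higher with DMBA may come from keratinocytes carried through the sort. With group means taken out, the markers had a median slope of 0.97 on the mean of the others (range 0.08 to 1.96, 31 markers), but any shared variation gives a slope near 1, so carried-over cells cannot be told apart from a change of these genes together. A lower share of melanocyte lineage cells cannot be told apart either: the log2 ratio of DMBA to vehicle was 0.92 (SE 0.25) for basal keratinocyte markers, and of the others immune cell markers parted from it by more than the summed SE (-0.20, SE 0.53) but fibroblast markers did not (0.48, SE 0.22). Schwann cell markers parted as a sum (0.06, SE 0.14). Their mean log2(FPKM + 1) was 0.19 higher in DMBA (exact permutation p = 0.3, two-sided), but their median was 1.12 higher (exact permutation p = 0.1, two-sided). Endothelial and pericyte markers did not rise, with sums between 34.9 and 47.4 FPKM in vehicle and between 28.7 and 40.2 FPKM in DMBA libraries. Immune, Schwann cell and endothelial sums thus go against a lower share, but fibroblast markers do not, so the question stays open. Whether DMBA itself changed the keratinocyte content was not tested.

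The AhR genes higher with DMBA may reflect the sorted cells or carried-over keratinocytes. Against more keratinocytes with no change per cell, 3 of 3 called AhR members stayed past the threshold with the keratinocyte covariate, with Cyp1a1 at a log2 fold change of 9.96 ± 0.58 (10.27 before), Cyp1b1 at 3.42 ± 0.49 (3.96 before) and Tiparp at 0.98 ± 0.17 (0.93 before). A response only in carried-over keratinocytes cannot be told apart from one in the sorted cells, because the basal keratinocyte level differed only 1.56-fold between the highest and lowest DMBA libraries.

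The 10 splits of 6 libraries into 2 groups of 3 are too few for a share under 0.05. In each pairwise comparison 1 of the 10 splits, the real one, gave as many genes: 118 for IR (highest other 0), 6 for DMBA (highest other 2) and 157 for IR against DMBA (highest other 0). For the test among the 3 groups, 1 of 100 drawn from 280 groupings gave as many, the real one with 171 against 143 for the highest other, which argues against chance alone. The 2 other groupings that kept the IR libraries together gave 136 and 143, and the 97 that parted them at most 6.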
